A study of Homo sapiens with 9 samples.

How the data were processed

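Poly-A RNA was sequenced from HMEC-1 cells, an immortalised line of human dermal microvascular endothelium grown at 5.5 mM glucose. Cells were exposed for 16 h to AMI-1 or AMI-5, each at 100 µM, or to the solvent DMSO, with 3 libraries per group and 9 in all. Both compounds are described by the study as pharmacological inhibitors of methyltransferases. The labels do not state that the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries.

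The authors deposited a pair of tables of raw read counts per gene, 1 for each compound, with the control libraries in each. BWA, bedtools and the genome build hg19 are named in the submitters' processing notes. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here. There were 18385 genes in the table for AMI-1 and 18598 in that for AMI-5, of which 18293 were in both. Control counts were identical in the tables, with 0 values that differed. The smallest mean count per gene was 10 in each table, a filter that favours genes higher with that table's compound. For that reason the comparisons used genes present in both tables, and the genes found in a single table were tested apart. Multi-copy small RNAs, pseudogenes, overlapping genes and antisense transcripts cannot be separated from their relatives in counts of unknown strand. No coordinates are given, since the reference annotation is on another assembly (GRCh38) than the counts.

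Total counts ran from 14454113 to 24693020 per library. The top gene in each library, FN1, held at most 1.10% of counts. Precision was tested on simulated data drawn from the blocked fit of these counts, which favours that fit. Changes of 1.5-fold, 2-fold and 4-fold were put into 67, 67 and 66 genes of 18284, all with an average log2 CPM above 1. The fit without a block recovered 1.5%, 26.9% and 80.3% of them in the AMI-1 comparison and 1.5%, 32.8% and 84.8% in the AMI-5 comparison. With the replicate block recovery was 82.1%, 97.0% and 100%, and 79.1%, 95.5% and 100%, while 19 and 11 unchanged genes were called.

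Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation and filterByExpr by group, which removed 9 genes and left 18284. A single fit of the 9 libraries gave the 3 contrasts: AMI-1 against control, AMI-5 against control, and AMI-5 against AMI-1. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and intervals are at 95%. Standard errors are those implied by the F test. Log2 CPM values used a prior count of 2. The groups, the contrasts, the fit without a block, the alternatives, the 36 gene lists and the rule for naming genes were fixed before the data were examined.

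Libraries carry replicate numbers 1 to 3, and the column names share a prefix within a number, but the labels do not say what the numbers have in common. Pairing was therefore checked by correlating, across genes, each library's deviation from its group's mean. Because all 9 libraries correlated best with a library of their own number, a second fit with replicate number as a block is given beside the first. Reporting named genes from the blocked fit, and the GC correction described next, were chosen after seeing the data.

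The GC correction fitted, for each library, a lowess curve (span 0.3) of the deviation in log2 CPM on transcript GC content over 14761 genes with an average log2 CPM above 1, and used it as an offset in the blocked fit. GC content came from the longest GENCODE transcript per gene. It was known for 17505 genes, 95.7% of those tested.

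Of the 36 lists, 34 had at least 5 measured members and were tested with camera in limma 3.58.1, first with a preset inter-gene correlation of 0.01 and then with a correlation estimated per list. The rotation test fry was run beside it. Its directional form is meant unless stated, which asks only whether a list's genes move on balance in 1 direction. Calls among a list's members are given both over all genes tested and adjusted over the list alone. Medians, signs and calls of members are from the blocked fit. The adjusted p of a list is from the fit without the block unless stated.

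The named genes follow a rule. For each compound they are the 10 largest rises and the 10 largest falls among genes past the threshold, with a mean CPM of at least 5 in the higher group and every library of a group on the same side of all those of the other. For the direct contrast 5 in each direction were taken. Up to 4 members of each described list with the lowest adjusted p (3 in the direct contrast) were added, together with PRMT1, CARM1, PRMT5 and SETD7. The rule was applied to the blocked fit because the fit without the block called no gene. Genes outside the rule are pointed out where they appear.

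Other settings fixed in advance were DESeq2 size factors in edgeR, no filter on low counts, the Wald test of DESeq2 1.42.0, a fit of only the 2 groups compared, the replicate block, the omission of each library in turn, and the other set tests. Later additions were the same alternatives within the blocked fit, the GC correction and the omission of all libraries of a replicate number. The effect of a shared control on the likeness of the compounds was simulated 20 times. Figures were drawn with matplotlib 3.10.9.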

Results

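Messenger RNA of HMEC-1 endothelial cells was compared after 16 h with AMI-1, with AMI-5 or with DMSO alone, 3 libraries per group. AMI-1 is a bis-naphthol sulfonic acid urea and AMI-5 a brominated xanthene dye, and the study used them to inhibit methyltransferases. Total counts were 15545005, 16610854 and 23401085 in control replicates 1, 2 and 3. They were 14561667, 17699870 and 24693020 with AMI-1, and 20969842, 14454113 and 23144429 with AMI-5. The fibronectin gene FN1 held the largest share of counts in each of the 9 libraries, 0.829% to 1.10%. Mitochondrially encoded transcripts held 2.20% to 3.59%.

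Libraries differed more by replicate number than by treatment. Replicate numbers accounted for 77.2% of the sum of squares between libraries and treatments for 11.1%. The 9 pairs with the same number correlated at 0.431 to 0.871 in their deviations from the group means, across genes that are not independent replicates. Pairs with different numbers ranged from -0.804 to 0.204. The biological coefficient of variation was 23.7% without a term for the replicate number and 5.64% with it. Without that term edgeR called 0, 0 and 0 genes in AMI-1 against control, AMI-5 against control and AMI-5 against AMI-1, with 187, 485 and 478 genes at an unadjusted p under 0.05. DESeq2 called 3, 19 and 36 in the same design. The 3 with AMI-1 were CYP1B1 (2.94, adjusted p = 8.6e-12), SHISA2 (0.78, adjusted p = 1.08e-05) and AKAP12 (0.31, adjusted p = 0.005), the last named after its values were seen. With the replicate block the edgeR counts were 75, 2002 and 932. All rises and falls given for single genes are from the blocked fit, and each named one went the same way in 3 of 3 pairs of libraries unless stated.

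**Figure D1:**
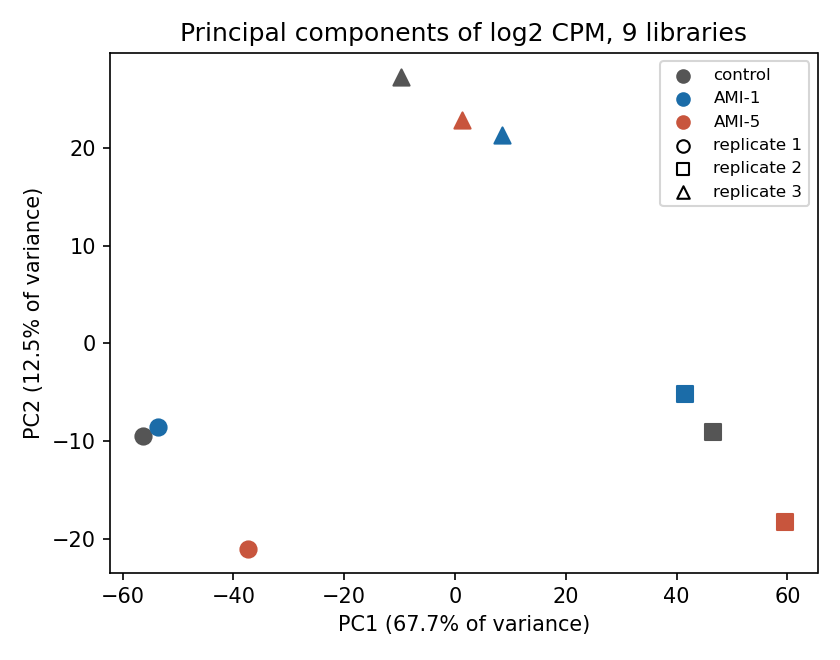
Principal components of log2 CPM in the 9 libraries, with 1 point per library, colour for treatment and shape for replicate number. The first component (67.7% of the variance, horizontal axis) and the second (12.5%, vertical axis) group the libraries by replicate number.

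AMI-1 against control asked which transcripts respond to the first inhibitor. CYP1B1, which encodes a cytochrome P450 transcribed under the aryl hydrocarbon receptor, rose 7.45-fold, from 5.74 ± 1.13 to 44.0 ± 19.9 CPM (SD, n = 3; log2 fold change 2.90 ± 0.19 SE, adjusted p = 1.52e-05). A pair of further targets of this receptor rose with it: TIPARP, an ADP-ribosyltransferase gene, by 0.86 ± 0.09 (adjusted p = 4.05e-05), and AHRR, the receptor's repressor, by 0.69 ± 0.09 (adjusted p = 0.000716). MMP1, the interstitial collagenase, rose 1.95-fold, from 53.9 ± 8.28 to 107.4 ± 35.3 CPM (0.96 ± 0.11, adjusted p = 0.000635). WTAPP1, a pseudogene beside MMP1 whose reads may not be separable from it at unknown strand, rose by 0.96 ± 0.11 (adjusted p = 0.000172). SHISA2, which encodes a retainer of WNT and FGF receptors in the endoplasmic reticulum, rose by 0.78 ± 0.08 (adjusted p = 3.7e-05). Among falls, the growth factor gene GDF6 changed by -0.50 ± 0.07 (adjusted p = 0.00145), the apelin gene APLN by -0.49 ± 0.08 (adjusted p = 0.00516), IGFBP3 by -0.42 ± 0.07 (adjusted p = 0.007) and the cyclin gene CCND1 by -0.30 ± 0.05 (adjusted p = 0.00854). Without AMI-1 replicate 3 the call of CYP1B1 ended (adjusted p = 0.0694) and so did that of MMP1 (adjusted p = 0.214). APLN and CCND1 lost theirs without control replicate 1, control replicate 3 or AMI-1 replicate 1 (adjusted p up to 0.167 and 0.215), and IGFBP3 without control replicate 1 or AMI-1 replicate 1 (up to 0.164). GC correction ended the call of MMP1 (0.94, adjusted p = 0.0609).

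Smaller rises with AMI-1 included LIF, a cytokine of the interleukin 6 family (0.58 ± 0.10, adjusted p = 0.0066), and NDRG1, a gene induced by low oxygen (0.40 ± 0.06, adjusted p = 0.00206). STC2, a secreted glycoprotein gene, rose by 0.47 ± 0.08 (adjusted p = 0.00761) and VEGFA, the vascular growth factor, by 0.31 ± 0.07 (adjusted p = 0.0489). LIF lost its call without control replicate 1, control replicate 3 or AMI-1 replicate 1 (adjusted p up to 0.143), NDRG1 without AMI-1 replicate 1 (0.0989). STC2 lost it without these 3 or AMI-1 replicate 3 (up to 0.452) and with GC correction (adjusted p = 0.209). VEGFA lost it without any control library, AMI-1 replicate 1 or AMI-5 replicate 1 or 2 (up to 0.427).

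The blocked fit called 42 genes higher and 33 lower with AMI-1, of which 21 changed over 1.5-fold and 10 over 2-fold. Call numbers moved with single libraries: 19 without control replicate 1, 27 without control replicate 3, 14 without AMI-1 replicate 1, 354 without AMI-1 replicate 2, 138 without AMI-1 replicate 3 and 159 without AMI-5 replicate 3. Of the 28 named genes called, 5 kept their call in all 9 fits without a library: WTAPP1, TIPARP, SHISA2, GDF6 and AHRR. With GC correction 624 genes were called, among them 72 of the 75.

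Among gene lists, ribosome biogenesis and MYC targets lay lower with AMI-1, with 42 of 42 members below 0 and a median of -0.17 (camera adjusted p = 4.55e-15). Over all genes 0 of them were called, against 23 lower with GC correction, and 27 fell adjusted over the list alone; the nucleophosmin gene NPM1 had -0.24 (adjusted p = 0.0902). Aryl hydrocarbon receptor targets lay higher (adjusted p = 4.55e-15), with 7 of 9 measured members above 0 and 2 below. Their median was 0.186 and their mean 0.555, raised above all by CYP1B1. Over all genes 3 of the 9 rose (6 rising and 1 falling with GC correction), and 5 did adjusted over the list alone. Those 2 lists alone held with a correlation estimated per list (adjusted p = 0.0119 and 0.0123), and with the block added they no longer did (0.152 and 0.146, and 0.1697 for each with GC correction). NF-kB and inflammatory adhesion genes lay higher (adjusted p = 3.69e-06; adjusted p = 0.0830 with an estimated correlation), with 1 of 20 rising (3 rising and 1 falling with GC correction) and, adjusted over the list alone, 8 rising and 1 falling. Hypoxia and glycolysis genes lay higher (adjusted p = 0.000877; adjusted p = 0.252 with an estimated correlation), with 2 of 35 rising, 9 with GC correction and 10 adjusted over the list alone. Actin and SRF target genes lay lower (adjusted p = 0.00114; adjusted p = 0.261 with an estimated correlation), with 0 of 28 called, 6 falling with GC correction and 8 adjusted over the list alone.

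Cytosolic ribosomal protein genes lay lower with AMI-1 in 72 of 77 members (adjusted p = 2.85e-05; adjusted p = 0.340 with an estimated correlation), and 0 were called over all genes or over the list alone, but 4 fell with GC correction. Fatty acid synthesis genes lay lower in 13 of 14 (adjusted p = 0.00368; adjusted p = 0.0830 with an estimated correlation), with 0 called and 5 falling with GC correction or adjusted over the list alone. Interferon response genes lay higher in 24 of 28 (adjusted p = 0.00368; adjusted p = 0.0830 with an estimated correlation), with 0 called, 1 rising with GC correction and 3 adjusted over the list alone. Matrix metalloproteinase and protease genes lay higher (adjusted p = 0.00568; adjusted p = 0.0883 with an estimated correlation), with MMP1 alone rising among 21, 3 rising and 1 falling with GC correction, and 2 rising adjusted over the list alone. Heat shock genes lay lower (adjusted p = 0.0232; adjusted p = 0.113 with an estimated correlation) and splicing factor genes too (adjusted p = 0.0325; adjusted p = 0.388 with an estimated correlation), with 0 of 26 and 0 of 49 called over all genes or over the list alone, and 5 and 4 falling with GC correction. Mitochondrially encoded transcripts lay higher in 13 of 13 (adjusted p = 0.0263; adjusted p = 0.785 with an estimated correlation), with 0 called and 3 rising with GC correction or adjusted over the list alone. With the block, metallothionein genes passed as well, higher (adjusted p = 0.0238; adjusted p = 0.263 with an estimated correlation), and so did TGF-beta and matrix genes, lower (adjusted p = 0.0477; adjusted p = 0.630 with an estimated correlation). GC correction ended the call of the latter (adjusted p = 0.0754). Of 34 lists 12 passed, but 6 did without control replicate 2 and 7 without AMI-1 replicate 1.

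AMI-5 against control asked the same of the second inhibitor. POLR2A, which encodes the largest subunit of RNA polymerase II, fell to 0.522 of control, from 719.8 ± 108.5 to 374.7 ± 43.4 CPM (SD, n = 3; -0.94 ± 0.05, adjusted p = 2.84e-09). PCIF1, the gene of a methyltransferase that binds the polymerase's tail, changed by -0.94 ± 0.08 (adjusted p = 1.97e-06) and the selenoprotein gene SEPW1 by -0.91 ± 0.08 (adjusted p = 1.49e-06). CLASP1, a microtubule-binding protein gene, changed by -0.81 ± 0.06 (adjusted p = 3.23e-07) and HHAT, an acyltransferase gene, by -0.77 ± 0.12 (adjusted p = 0.00111). Rises were led by VSIG2, an immunoglobulin-domain protein gene, at 3.45-fold but low counts, from 1.55 ± 0.22 to 5.28 ± 0.56 CPM (1.79 ± 0.17, adjusted p = 9.49e-06), and by the glycosyltransferase gene GBGT1 (1.62 ± 0.17, adjusted p = 2.24e-05). SLC7A11, the cystine transporter gene, rose 1.99-fold (0.99 ± 0.08, adjusted p = 7.58e-07), the asparagine synthetase gene ASNS by 0.84 ± 0.08 (adjusted p = 8.96e-06) and the quinone reductase gene NQO1 by 0.57 ± 0.06 (adjusted p = 3.09e-05). These 10 genes kept their calls in all 9 fits without a library and with GC correction.

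HMOX1, the heme oxygenase gene, rose 2.18-fold with AMI-5 (1.13 ± 0.23, adjusted p = 0.0197), by 0.64, 1.84 and 0.85 in the 3 pairs. Its call ended without control replicate 1, control replicate 3, AMI-1 replicate 3 or AMI-5 replicate 3 (adjusted p up to 0.118) and with GC correction (1.25, adjusted p = 0.0791).

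**Figure D2:**
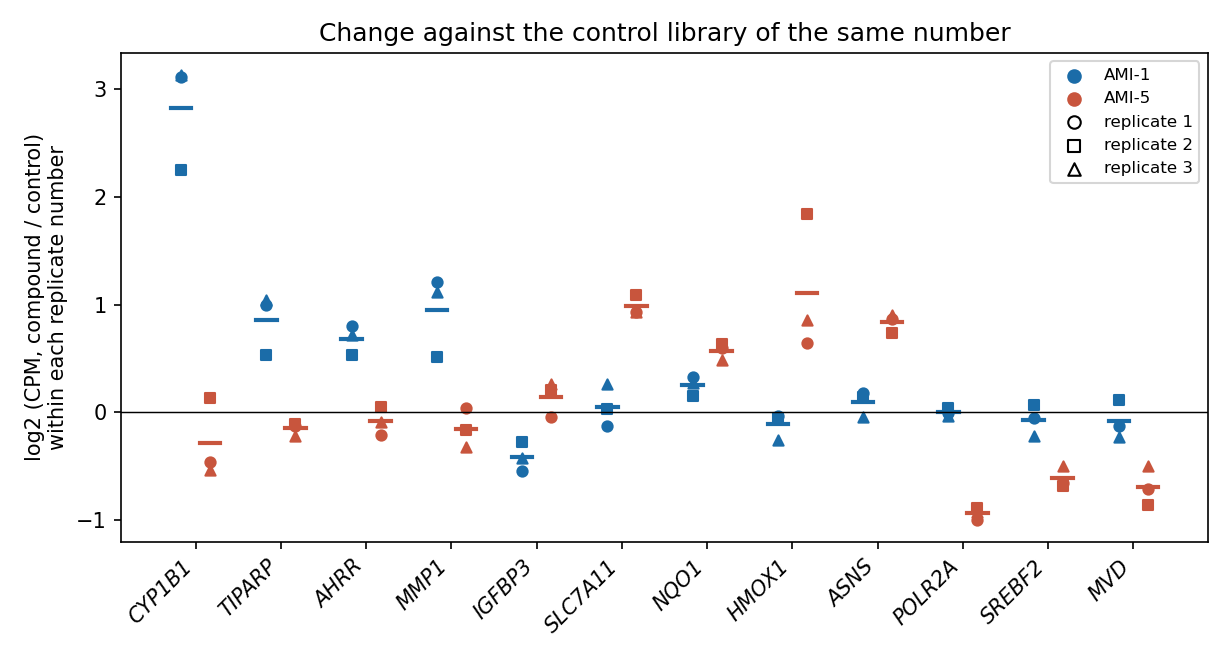
Log2 CPM of compound over control within each replicate number for 12 genes, with 1 point per replicate number and a bar at their mean. CYP1B1, TIPARP, AHRR and MMP1 are higher with AMI-1, by 2.90, 0.86, 0.69 and 0.96 in the blocked fit, while POLR2A, SREBF2 and MVD are lower with AMI-5, by -0.94, -0.60 and -0.66.

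The blocked fit called 629 genes higher and 1373 lower with AMI-5, of which 211 changed over 1.5-fold and 39 over 2-fold. Genes called lower had a median transcript GC content of 58.8% and genes called higher one of 41.5%, against 48.1% of all tested. With GC correction 2487 genes were called, of which 1348 were among the 2002, 457 higher and 891 lower. The number also depended on single libraries: 320 without control replicate 1, 281 without control replicate 3, 1304 without AMI-1 replicate 1, 4283 without AMI-1 replicate 3, 155 without AMI-5 replicate 1 and 310 without AMI-5 replicate 2. Of the 122 named genes called, 33 kept their call in all 9 of those fits.

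**Figure D3:**
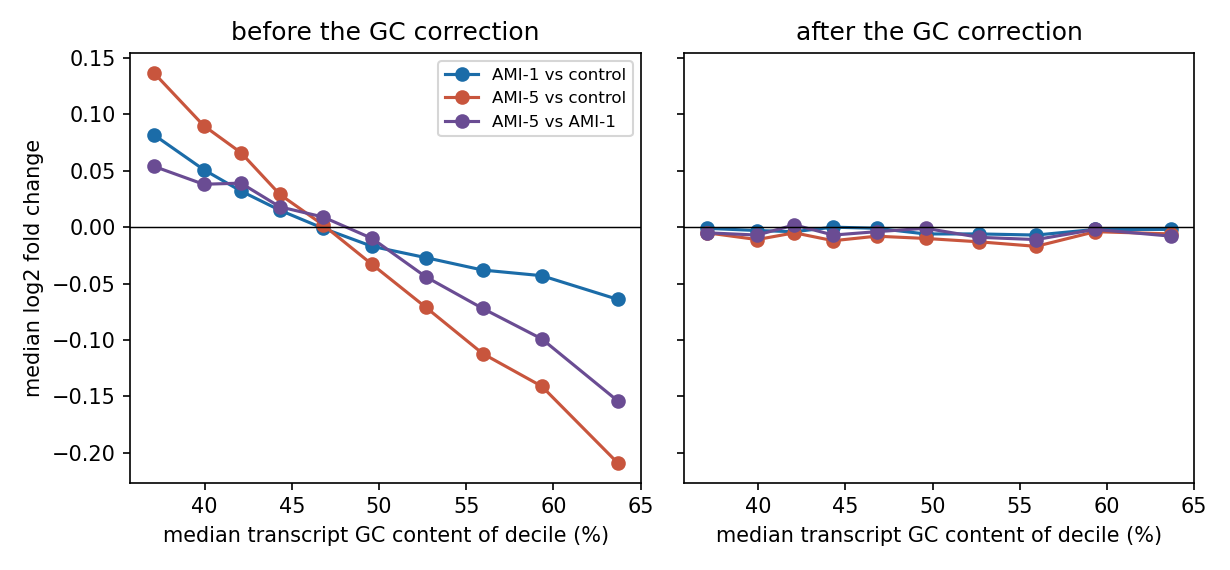
Median log2 fold change of genes in equal bins of transcript GC content (vertical axis) against the median GC percentage of the bin (horizontal axis), for the 3 comparisons before and after GC correction. With AMI-5 against control the uncorrected medians run from 0.14 at 37.1% GC to -0.21 at 63.7% GC.

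Targets of NRF2, the regulator of antioxidant genes, lay higher with AMI-5 (camera adjusted p = 1.82e-05), with 9 of 32 rising over all genes, 17 with GC correction and, adjusted over the list alone, 10 rising and 1 falling. Beside SLC7A11 and NQO1 they included GCLM, the glutamate-cysteine ligase modifier gene (0.53 ± 0.08, adjusted p = 0.000753). This list alone held with an estimated correlation (adjusted p = 0.0414), with the block added it no longer did (0.112), and with block and GC correction it did again (0.0335). Amino acid response genes under ATF4 lay higher (adjusted p = 4.67e-05; adjusted p = 0.134 with an estimated correlation), with 8 of 38 rising, 18 rising and 1 falling with GC correction, and 13 rising adjusted over the list alone. PSAT1, of serine synthesis, rose by 0.47 ± 0.06 (adjusted p = 0.000325).

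Cholesterol synthesis and uptake genes lay lower with AMI-5 (adjusted p = 0.000716; adjusted p = 0.0732 with an estimated correlation), with 9 of 25 falling, 13 falling and 1 rising with GC correction, and 10 falling adjusted over the list alone. SREBF2, which encodes their transcription factor, changed by -0.60 ± 0.07 (adjusted p = 7.91e-05), MVD by -0.66 ± 0.09 (adjusted p = 0.000336) and LSS by -0.42 ± 0.06 (adjusted p = 0.000885). Fatty acid synthesis genes lay lower (adjusted p = 0.0123; adjusted p = 0.134 with an estimated correlation), with 5 falling and 1 rising of 14, 8 and 1 with GC correction, and 6 and 1 adjusted over the list alone. SCD, the stearoyl-CoA desaturase gene, changed by -0.35 ± 0.05 (adjusted p = 0.00106), and SREBF1 by -0.59 ± 0.09 (adjusted p = 0.000826), a call lost without AMI-5 replicate 1 (adjusted p = 0.0539).

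Matrix genes of the TGF-beta response lay lower with AMI-5 (adjusted p = 0.00865, or 0.336 with an estimated correlation), with 11 falling and 2 rising of 42, and 18 and 4 adjusted over the list alone. GC correction brought their median from -0.13 to -0.038, with 8 falling and 2 rising (camera adjusted p = 0.0367 with block and GC correction). Actin and SRF target genes lay lower (adjusted p = 0.00592; adjusted p = 0.352 with an estimated correlation), with 10 of 28 falling and 13 adjusted over the list alone. Ribosome biogenesis genes lay lower (adjusted p = 0.00475; adjusted p = 0.134 with an estimated correlation), with 7 of 42 falling and, adjusted over the list alone, 12 falling and 1 rising. Interferon response genes lay higher (adjusted p = 0.0116; adjusted p = 0.134 with an estimated correlation), with SAMD9 rising among 28 and adjusted over the list alone (0.36 ± 0.08, adjusted p = 0.00864), and 3 rising and 1 falling with GC correction. SAMD9 lost its call without control replicate 1 or 3 or AMI-5 replicate 1 or 2 (adjusted p up to 0.120). With the block, mitochondrially encoded transcripts passed too, higher (adjusted p = 0.00291; adjusted p = 0.651 with an estimated correlation), with 3 of 13 rising over all genes and adjusted over the list alone, and 2 with GC correction. So did cytosolic ribosomal protein genes, lower (adjusted p = 0.0495; adjusted p = 0.731 with an estimated correlation), with 9 of 77 falling and 10 adjusted over the list alone. GC correction ended the call of the latter (adjusted p = 0.0606), with 7 falling and 3 rising.

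Endothelial identity genes lay lower with AMI-5 (adjusted p = 0.0245, or 0.618 with an estimated correlation), with 8 falling and 1 rising of 25, and 10 and 1 adjusted over the list alone. PECAM1, CLDN5, MMRN1, LYVE1 and PROX1 of this list were not among the genes tested. The endoglin gene ENG changed by -0.36 ± 0.07 (adjusted p = 0.00362) and the VE-cadherin gene CDH5 by -0.28 ± 0.06 (adjusted p = 0.008). ESAM, an adhesion molecule gene at low counts, rose from 1.15 ± 0.52 to 2.80 ± 0.07 CPM (1.25 ± 0.23, adjusted p = 0.00327). After GC correction 5 members fell and camera gave an adjusted p of 0.0974. Smooth muscle and pericyte markers had a similar median, -0.17 against -0.19, with 3 falling and 1 rising of 9 in the blocked fit (adjusted p = 0.149) and 2 and 1 after GC correction (adjusted p = 0.230). GC correction brought these medians to -0.042 and -0.055. ENG lost its call without control replicate 1 or AMI-5 replicate 1 or 2 (adjusted p up to 0.0905), CDH5 also without control replicate 3 (up to 0.103).

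Genes of the methyltransferase lists were called against control with AMI-5 but not with AMI-1 in the blocked fit, which called 2002 and 75 genes in all. With GC correction 2 members of the arginine list and 2 of the DNA and RNA list fell with AMI-1, and 0 of the lysine list. PRMT1, of the main arginine methyltransferase, changed by -0.34 ± 0.06 (adjusted p = 0.00158), a call lost without AMI-5 replicate 1 (adjusted p = 0.0523). PRMT5 changed by -0.20 ± 0.06 (adjusted p = 0.0285), lost without 7 of the 9 libraries, all but AMI-1 replicates 2 and 3 (adjusted p up to 0.209). CARM1 had -0.18 with an interval of -0.31 to -0.06 (adjusted p = 0.0581) and SETD7 0.00 (-0.13 to 0.12, adjusted p = 0.979). With AMI-1 the values were -0.18 for PRMT1 (-0.30 to -0.06, adjusted p = 0.232), -0.03 for CARM1 (-0.16 to 0.10, adjusted p = 0.902) and 0.00 for SETD7 (-0.13 to 0.12, adjusted p = 0.990). PRMT5 had -0.11 there (-0.23 to 0.00, adjusted p = 0.504), and GC correction brought PRMT1 past the threshold with AMI-1 (-0.15, adjusted p = 0.00707). The lysine methyltransferase gene DOT1L changed with AMI-5 by -0.58 ± 0.08 (adjusted p = 0.00029) and the demethylase gene KDM5C by -0.41 ± 0.06 (adjusted p = 0.000489).

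AMI-5 against AMI-1 asked whether the inhibitors differ at equal dose and time. CYP1B1 was lower with AMI-5, at 4.64 ± 0.24 against 44.0 ± 19.9 CPM (SD, n = 3; -3.24 ± 0.20, adjusted p = 8.27e-07), as were TIPARP (-1.01 ± 0.09, adjusted p = 1.14e-06) and AHRR (-0.79 ± 0.09, adjusted p = 3.89e-05). MMP1 differed by -1.12 ± 0.11 (adjusted p = 2.72e-05), SHISA2 by -1.10 ± 0.08 (adjusted p = 8.97e-08) and LIF by -0.90 ± 0.10 (adjusted p = 2.08e-05). Higher with AMI-5 were GBGT1 (1.66 ± 0.17, adjusted p = 7.43e-06), VSIG2 (1.59 ± 0.17, adjusted p = 1.37e-05), SLC7A11 (0.92 ± 0.08, adjusted p = 1.07e-06) and ASNS (0.75 ± 0.08, adjusted p = 1.47e-05). DANCR, a non-coding transcript that hosts a small nucleolar RNA, was higher by 0.87 ± 0.08 (adjusted p = 3.25e-06). These 11 genes kept their calls in all 9 fits without a library and with GC correction. HMOX1 was higher by 1.25 ± 0.23 (adjusted p = 0.0212), which ended without AMI-1 replicate 2, AMI-1 replicate 3 or AMI-5 replicate 3 (adjusted p up to 0.208) and with GC correction (adjusted p = 0.0767).

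Between the compounds PRMT1 differed by -0.16 (-0.28 to -0.04, adjusted p = 0.126), PRMT5 by -0.08 (-0.20 to 0.03, adjusted p = 0.436), CARM1 by -0.15 (-0.28 to -0.03, adjusted p = 0.160) and SETD7 by 0.00 (-0.12 to 0.13, adjusted p = 0.997). None of these 4 passed the threshold, so a call with AMI-5 and none with AMI-1 does not show that the compounds differ there. Other members of the methyltransferase lists did differ, with 1 of 16 arginine and 5 of 47 lysine list members called, all lower with AMI-5. With GC correction 1 was lower and 1 higher of the former, and 9 lower of the latter. They include KDM5C (-0.36 ± 0.06, adjusted p = 0.00118), which kept its call in all 9 fits without a library. PRMT6 (-0.39 ± 0.08, adjusted p = 0.00667) lost its call without AMI-1 replicate 1 or AMI-5 replicate 1 or 2 (adjusted p up to 0.107), and DOT1L (-0.44 ± 0.08, adjusted p = 0.00208) without AMI-1 replicate 1 or AMI-5 replicate 1 (up to 0.0788). The blocked fit called 296 genes higher and 636 lower with AMI-5 than with AMI-1, 146 over 1.5-fold and 40 over 2-fold. GC correction gave 2156 calls, among them 888 of the 932. Without a single library the number was 621 for control replicate 1, 194 for AMI-1 replicate 1, 589 for AMI-1 replicate 2, 3465 for AMI-1 replicate 3, 192 for AMI-5 replicate 1, 292 for AMI-5 replicate 2 and 1503 for AMI-5 replicate 3. Of 71 named genes called, 31 kept their call in all 9 fits without a library.

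In this direct contrast ATF4 response genes were higher with AMI-5 (adjusted p = 8.31e-07; adjusted p = 0.0645 with an estimated correlation), with 8 higher and 2 lower of 38, 26 and 2 with GC correction, and 20 and 2 adjusted over the list alone. NRF2 targets were higher (adjusted p = 6.95e-06), with 7 of 32 higher, 13 higher and 1 lower with GC correction and, adjusted over the list alone, 10 and 1. NRF2 targets alone held with an estimated correlation (adjusted p = 0.0425), and with the block added they no longer did (0.0981). With block and GC correction NRF2 targets and ATF4 response genes each held (0.0424 for each). Aryl hydrocarbon receptor targets were lower with AMI-5 (adjusted p = 3.99e-06; adjusted p = 0.0569 with an estimated correlation), with 3 lower and 2 higher of 9, and 5 and 2 with GC correction or adjusted over the list alone. NF-kB genes were lower (adjusted p = 2.26e-05; adjusted p = 0.0674 with an estimated correlation), with 4 of 20 called, 6 lower and 1 higher with GC correction, and 6 lower adjusted over the list alone. Metalloproteinase and protease genes were lower (adjusted p = 6.88e-05; adjusted p = 0.0569 with an estimated correlation), with 5 of 21 called and 6 adjusted over the list alone. Cholesterol genes were lower (adjusted p = 0.000733; adjusted p = 0.0569 with an estimated correlation), with 6 of 25 called, 11 with GC correction and 8 adjusted over the list alone; SREBF2 differed by -0.54 ± 0.07 (adjusted p = 0.000129).

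Endothelial identity genes were also lower with AMI-5 than with AMI-1 (adjusted p = 0.00213; adjusted p = 0.403 with an estimated correlation), with 6 lower and 1 higher of 25, 9 and 2 with GC correction, and 11 and 1 adjusted over the list alone. Smooth muscle and pericyte markers had a median of -0.12 there against -0.17, with 2 lower and 1 higher of 9; GC correction brought these medians to -0.085 and -0.097. Hypoxia genes were lower (adjusted p = 0.0113; adjusted p = 0.374 with an estimated correlation), with 5 lower and 2 higher of 35, 9 and 2 with GC correction, and 7 and 2 adjusted over the list alone. NDRG1 differed by -0.48 ± 0.06 (adjusted p = 8.38e-05), VEGFA by -0.42 ± 0.07 (adjusted p = 0.00106) and ANGPTL4, also of that list, by 0.75 ± 0.10 (adjusted p = 9.7e-05). Heat shock genes were higher (adjusted p = 0.00456; adjusted p = 0.0645 with an estimated correlation), with 4 higher and 2 lower of 26, 7 and 2 with GC correction, and 5 and 2 adjusted over the list alone. Ribosome biogenesis genes were higher (adjusted p = 0.0187; adjusted p = 0.203 with an estimated correlation), with TAF1D called among 42, 6 higher with GC correction and 0 adjusted over the list alone. The call of TAF1D ended without control replicate 1 or 3, AMI-1 replicate 1 or 2, or AMI-5 replicate 1 or 2 (adjusted p up to 0.345). With the block, immediate early genes passed as well, lower (adjusted p = 0.0327; adjusted p = 0.831 with an estimated correlation), a call that GC correction ended (adjusted p = 0.346). So did lysine methyltransferase and demethylase genes, lower (adjusted p = 0.0321; adjusted p = 0.206 with an estimated correlation).

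Genes called with each compound in the same direction numbered 16 in the blocked fit, all lower, where independent lists would share 2.48 lower and 1.44 higher, without regard to the shared control. The 16 include APLN, CCND1 and the neuropilin gene NRP2 (-0.30 and -0.25). NRP2 lost its call with AMI-1 without any control library, AMI-1 replicate 1 or AMI-5 replicate 1 or 2 (adjusted p up to 0.483), and with DESeq2 size factors, the DESeq2 test or the 2 groups alone. With AMI-5 it lost its call without control replicate 1 or 3, AMI-1 replicate 1 or AMI-5 replicate 1 or 2 (up to 0.235). With GC correction 159 genes were lower with each compound, 46 higher with each and 27 opposite. The 3 genes called in opposite directions without that correction were SHISA2 (0.78 and -0.32), ANPEP (0.32 and -0.43) and IGFBP4 (0.52 and -0.28), all higher with AMI-1, and the latter pair was picked after the values were seen. GC correction ended the fall of IGFBP4 with AMI-5 (adjusted p = 0.599). Across genes the log2 fold changes of the compounds correlated at 0.477, with a covariance of 0.0213 (0.445 and 0.018 with GC correction). A shared control raises such figures by itself. In 20 simulations without any effect the correlation averaged 0.513 and the covariance 0.0130, with a maximum of 0.0139. The simulated groups held no GC difference, so the larger covariance in the data cannot be read as likeness of the compounds alone. With at most 3 and 2 genes called per compound, these simulations set no expectation for the number shared. The 3 control libraries are too few to be split into separate sets for each compound. The number was 2 without control replicate 1, 4 without control replicate 3, 1 without AMI-1 replicate 1, 178 without AMI-1 replicate 2, 32 without AMI-1 replicate 3, 5 without AMI-5 replicate 1, 9 without AMI-5 replicate 2 and 57 without AMI-5 replicate 3.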

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

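The tests of sequencing depth, of GC content as the whole cause of the replicate differences, of the AMI-5 falls and of the aryl hydrocarbon receptor targets were chosen only after the result was seen, as were the small-RNA genes singled out here.

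Genes present in a single deposited table drew attention because the comparisons do not use them. With AMI-1, 2 of 55 tested were called against control, both higher, and with AMI-5, 35 of 218, all higher. Each table had its own blocked fit, and the adjusted p-values are over all genes of that fit. The 35 count SNORD3A under a pair of gene IDs with identical counts (36, 25 and 17 against 4, 7 and 4), and hold several entries of U1. The antisense transcript CYP1B1-AS1 rose by 3.26 ± 0.29 with AMI-1 (adjusted p = 2.76e-06) and CYP1A1 by 2.25 ± 0.33 (adjusted p = 0.00101), from 9, 5 and 7 counts in control to 28, 16 and 62. With AMI-5 the multi-copy small RNA genes SNORD3B-2 and RNU7-1 had 2.69 ± 0.26 and 2.22 ± 0.34, and ARC, an immediate early gene, 1.72 ± 0.32, with 26, 11 and 40 counts against 5, 4 and 12. The direction is partly built in, since a table's minimum mean count of 10 favours genes higher with its compound. Reads of the small RNAs cannot be assigned to single copies, and at unknown strand those of CYP1B1-AS1 cannot be separated from CYP1B1.

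Libraries with the same replicate number deviated together from their groups. Depth as the whole cause is argued against: replicate 1 was deeper than 2 with AMI-5 and less deep in the other groups, yet their difference correlated with those groups at 0.880 (control) and 0.873 (AMI-1); replicate 3 was the deepest in each group, so depth as part of the cause stays open. GC content as the whole cause is argued against as well, since 9 of 9 same-number correlations stayed above 0.1 after the correction (0.521 to 0.802). Part of the difference between replicate numbers did follow GC content, since the correction removed 38.8% of their sum of squares. That share lies between the limits set in advance for and against GC bias as the explanation. Whether bias of the libraries caused this part stays open. Shared culture days, library preparation or sequencing runs may also contribute, and neither they nor a biological explanation were tested.

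Genes that fell with AMI-5 were rich in GC, and GC content bias was weighed against a response to the compound. Over all 1373 falls the median was -0.30 before GC correction and -0.18 after it (quartiles -0.26 and -0.12), and 891 stayed called. These genes were picked for being lower in the same data. In the bin of genes richest in GC the median before correction was only -0.21. A median that stays below 0 is thus partly built in, and it does not decide on GC bias as the whole cause. For the 482 whose call ended the median moved from -0.27 to -0.10 (quartiles -0.14 and -0.08), so bias and a response that follows GC cannot be told apart there; the calls ended because the fold shrank, since the median standard error fell too, from 0.07 to 0.05. GC slopes also differed within control, AMI-1 and AMI-5: in log2 per 10% GC they were -0.65, -0.54 and -0.58 for replicate 2 against 1, -0.20, -0.32 and -0.10 for 3 against 1, and 0.45, 0.23 and 0.47 for 3 against 2. The 3 pairs of AMI-5 and control had -0.18, -0.10 and -0.08.

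The called aryl hydrocarbon receptor targets CYP1B1, TIPARP and AHRR rose with AMI-1, and a response to this compound is a candidate explanation. Over bins of GC content the median log2 fold change ran only from 0.08 to -0.06 with AMI-1, against a median of 0.86 for these genes. GC bias of that size is argued against as the cause of their rise. Their median of 0.83 after correction adds little, since so small a correction could not have halved it. Each gene rose in 3 of 3 pairs and kept at least 86.4% of its log2 fold change in the fits without a library. CYP1B1 still lost its call without AMI-1 replicate 3 (2.69, adjusted p = 0.0694). The blocked fit that picked these genes favours even rises over the pairs. Such evenness is thus partly built in and does not decide on a single library as the cause. A further test was met by 5 of 5 genes. CYP1B1, TIPARP and AHRR were higher with AMI-1 than with AMI-5 in all 3 pairs. The single-table genes CYP1A1 and CYP1B1-AS1 were higher with AMI-1 than in control in all 3. This decides nothing, since all were picked for being higher with AMI-1 than in control, and the same AMI-1 libraries enter each comparison. CYP1B1 changed by 3.11, 2.25 and 3.13 in the 3 pairs with AMI-1 and by -0.46, 0.13 and -0.53 with AMI-5, and a response to AMI-1 is given as a hypothesis, since it was found and tested on the same data.

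Other groupings of the 6 libraries of a comparison are too few for a share under 0.05. Without the block, the real split called 0 genes in each comparison and the highest other split 0, so 10 of 10 splits gave as many. Only 4 splits part every pair, and in the blocked fit the real 1 called 75, 2002 and 932 genes where the highest other called 0, 0 and 4.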

How the results depend on the processing

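The replicate block was fixed in advance as another setting, while its GC correction, the changes of setting within it and the omission of replicate numbers were chosen only after the result was seen; the cause was not tested for any shift given here unless stated. In the fit without the block, DESeq2 size factors and no filter on low counts left the counts at 0 in all 3 comparisons. The DESeq2 Wald test gave 3, 19 and 36 genes for AMI-1, AMI-5 and AMI-5 against AMI-1, and the replicate block 75, 2002 and 932, with 16 shared in direction. Without single libraries the unblocked counts ran from 0 to 1, stayed at 0, and ran from 0 to 2: CYP1B1 with AMI-1, and CYP1B1 and SHISA2 between the compounds, each without AMI-1 replicate 2.

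Against the blocked counts, no block gave 0, 0 and 0, and 0 shared. GC correction gave 624 genes with AMI-1, 2156 between the compounds and 205 shared, while 2487 with AMI-5 lay within 1.5 times of 2002. The DESeq2 Wald test gave 1152 with AMI-5 and 616 between the compounds, and the fit of only the 2 groups compared 4449 with AMI-5 and 26 shared. Without single libraries the counts ran from 14 to 354 with AMI-1, 155 to 4283 with AMI-5, 192 to 3465 between the compounds and 1 to 178 shared. Without all libraries of replicate number 1 they were 1 (CYP1B1), 24, 39 and 0, without number 2 they were 203, 1449, 453 and 69, and without number 3 they were 150, 2993, 3397 and 30. Fits without a number have fewer libraries.

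Gene lists past the set test, 12, 9 and 10 in the 3 comparisons, were 2, 1 and 1 with a correlation estimated per list, 3, 4 and 4 with fry, 0, 0 and 0 with the block and an estimated correlation, and 0, 1 and 2 when GC correction was added to that. The block with fry gave 2 with AMI-1 and 5 with AMI-5, and GC correction 14 with AMI-5. The 5 were NRF2 targets, the lysine methyltransferase list and the protease list (fry adjusted p = 0.0165 for each), fatty acid synthesis genes (0.0218) and cholesterol genes (0.0417). Without single libraries the numbers ran from 6 to 14, 6 to 11 and 8 to 13. The mixed form of fry, which asks for change in either direction, passed 11, 30 and 27 of 34 lists in the blocked fit.

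Of 221 named results called in the blocked fit, 0 changed direction in any alternative. They were picked from the same libraries for passing the threshold, so a kept direction is largely built in. Their calls held for 215 with DESeq2 size factors, 221 without the filter, 189 with DESeq2, 208 with the 2 groups alone, 196 with GC correction and 0 without the block. Without single libraries 91 to 213 held, and without replicate number 1, 2 or 3 it was 31, 165 and 213. Taking control libraries from the AMI-5 table gave no value, since 0 control values differ between the tables. In the blocked fit on simulated data 97.0% and 95.5% of 2-fold changes were recovered, but 1.5-fold changes were missed in part (82.1% and 79.1% recovered). Depth was not varied there and genes with the lowest counts received no change, so these figures do not show whether depth was limiting.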

Other observations

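The test of host transcripts was written before its result was seen, but only after DANCR and TAF1D had been found higher in the same data, and its weighing against control was chosen only after the result was seen.

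DANCR and TAF1D, which host small nucleolar RNAs, were higher with AMI-5 than with AMI-1, and a candidate explanation is that such host transcripts accumulate as a class with AMI-5. Among 13 other listed hosts measured of 17, the median was 0.21 (0.17 after GC correction), 12 were above 0, and 5 were called higher and 0 lower (GAS5, SNHG1, SNHG6, SNHG7 and SNHG12, picked after their values were seen). SNHG12 differed by 0.54 ± 0.07 (adjusted p = 0.000235). The camera test in the blocked fit gave p = 1.85e-07, and 0.00526 with an estimated correlation. Against control DANCR rose with AMI-5 (0.54 ± 0.08, adjusted p = 0.000713) and had -0.33 with AMI-1 (adjusted p = 0.107; adjusted p = 0.0161 with GC correction). TAF1D had 0.21 with AMI-5, higher in 3 of 3 pairs (adjusted p = 0.0624), and -0.04 with AMI-1, but 0.065 and -0.13 after GC correction. For the 13 other hosts the median against control was 0.05 with AMI-5 and -0.16 with AMI-1. These medians were not GC-corrected, and the hosts were not tested as a set against control. Neither accumulation as a class with AMI-5 nor a fall with AMI-1 is therefore shown.

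Of the 36 lists, 19 passed no set test in the fit without the block, a number that includes the untested keratinocyte and leukocyte lists. Marker lists of other cell types passed it in no comparison: fibroblast markers had 8 of 11 measured (camera adjusted p = 0.131 with AMI-1, 0.897 with AMI-5 and 0.179 between the compounds), and smooth muscle and pericyte markers 9 of 12 (0.325, 0.752 and 0.845). In the blocked fit with AMI-5 1 of the former fell, and 3 of the latter fell and 1 rose. The set test concerns change between groups and not whether such cells were present. Keratinocyte and leukocyte markers, with 4 of 13 and 3 of 12 measured, were too few for the set test. The protein arginine methyltransferase list gave adjusted p of 0.507, 0.229 and 0.668, and 3 of its 16 members fell with AMI-5 in the blocked fit. Lysine methyltransferases and demethylases gave 0.957, 0.161 and 0.0888, with 9 falling and 1 rising of 47 with AMI-5. DNA and RNA methyltransferases gave 0.229, 0.433 and 0.979, with 3 of 23 falling. Methionine cycle genes gave 0.801, 0.904 and 0.972.

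Genes of the p53 response gave 0.846, 0.812 and 0.782, although MDM2 rose with AMI-5 by 0.36 ± 0.06 (adjusted p = 0.0013). Mitosis genes gave 0.567, 0.515 and 0.895, and HMMR, a hyaluronan receptor gene of that list, fell with AMI-5 by 0.50 on the log2 scale (adjusted p = 0.00122). DNA replication genes gave 0.229, 0.281 and 0.896, chaperones of the endoplasmic reticulum 0.807, 0.897 and 0.792, and immediate early genes 0.508, 0.559 and 0.187. Coagulation genes gave 0.801, 0.904 and 0.972, Notch and KLF signalling genes 0.979, 0.173 and 0.129, and lysosome genes 0.105, 0.856 and 0.126. Nuclear genes of oxidative phosphorylation gave 0.793, 0.193 and 0.288, apoptosis regulators 0.550, 0.515 and 0.896, and metallothioneins 0.131, 0.953 and 0.309.

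Further results passed camera with the preset correlation only with block and GC correction. The ones given here did not pass with an estimated correlation as well. Of them, lysine methyltransferases and demethylases with AMI-5 had also passed fry in the blocked fit without GC correction (adjusted p = 0.0165). With AMI-1 lysosome genes lay higher (adjusted p = 0.00137; 0.1697 with an estimated correlation). With AMI-5 p53 targets lay higher (0.0488; 0.438), while splicing factor genes (0.000288; 0.438), mitosis genes (0.00271; 0.438), nuclear genes of oxidative phosphorylation (0.0127; 0.506) and lysine methyltransferases and demethylases (0.0353; 0.438) lay lower. Between the compounds metallothioneins were lower with AMI-5 (0.0141; 0.370) and cytosolic ribosomal protein genes higher (0.0263; 0.822).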
